A study of Mus musculus with 6 samples.

How the data were processed

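RNA sequencing was done on 6 libraries of mouse bone marrow-derived macrophages, 3 wild-type and 3 Senp8+/-, all given CD47-coated beads. Per the labels' protocols, marrow was cultured with GM-CSF, RNA was taken 24 h after the beads were given, and mRNA was selected by its poly(A) tail and copied with random primers. Whether the libraries keep strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used. The genome build, the annotation, the counting settings and the tool behind the test are not given in the sources used here. Groups came from the titles of the samples. The columns that the titles call KO hold the cells whose genotype label and series title name a heterozygote, and they are called Senp8+/- here.

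The deposited table has 1 row per gene. Its values per library are a signal made by the authors, read counts divided by 1 size factor per library, and the deposited means equal the means of the 3 libraries within 8.73e-11. In each library 100% of the values were whole multiples of 1 step, with a tolerance of 1e-06 of a read. The steps, as their inverse, gave size factors of 0.971, 1.07 and 0.933 for Senp8+/- replicates 1, 2 and 3 and 1.01, 0.947 and 1.14 for wild-type replicates 1, 2 and 3. The whole reads were recovered from them. The table also holds the authors' log2 fold change, Senp8+/- over wild type, with p-values and adjusted p-values as deposited by the authors. It lists 714 genes. Tested on the values, the largest p was 0.0499 and the smallest absolute log2 fold change 1.00, so the list was selected on both. The adjusted p of the top gene divided by its p gave 14694 genes in the authors' correction. In 40 rows the adjusted p is written as 1, and these rows have means of at most 2.69 normalised counts. They were treated as not past the threshold. A fold change fitted by DESeq2 on the recovered reads with the deposited size factors differed from that in the authors' deposited table by a median of 3.87e-04 on the log2 scale and at most 0.00939.

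The selection affects every measurement. The listed genes cannot give library depths or a scaling, a gene list test over all genes (camera, and its form with an estimated correlation) could not be run, and effects of listed genes are on average overstated. The deposited scaling was therefore kept. The reads over the listed genes per library ranged from 205957 to 491156, and total depths are unknown here. Gene positions are those of the deposited table. Of the 714 gene identifiers, 714 were in the GENCODE M21 annotation of GRCm38, 687 with the same start and end and 713 with the same symbol, and these positions are named as GRCm38 on that basis. Senp8 was located with that annotation. No columns of samples outside this series were present (0).

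The design fixed before the data were examined foresaw a table of selected genes. In that case it asked for the counts of listed genes in each direction and for limma as a description of the listed genes. limma 3.58.1 (R 4.3.3; empirical Bayes with a mean-variance trend) was fitted to log2(value + 1) over the 714 genes, with genotype as the only term. Fold changes on this scale understate those of low genes. Its p-values were adjusted by Benjamini-Hochberg over 14694 genes, the genes not listed taken to have larger p-values. The threshold was an adjusted p of 0.05. A gene is described as having risen or fallen where the adjusted p in the authors' deposited table is under 0.05. A fold against libraries with 0 reads was computed against a floor of 3 reads per library, 3.03 normalised counts in Senp8+/- and 2.92 in wild type, and covers counting error only.

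The genes named are Senp8 and listed neddylation genes, then, among called genes without overlap between genotypes, with a mean of at least the table's median of 26.8 and with a symbol that is not that of a predicted gene, the 8 with the largest and the 8 with the smallest log2 fold change. Added to these are the 5 called genes of highest mean in each direction and up to 4 members of each list with the smallest p. The rule gave 84 genes, of which 2, and the results that need them, are not reported here. Others are said to have been chosen after their values were seen. The 29 gene lists (24 with a listed member) were fixed before the data were examined. For lists with at least 5 listed members the split into higher and lower was tested against the other listed genes (two-sided Fisher exact test, Benjamini-Hochberg over 10 lists). Over-representation of list members among the called genes was tested against the 14694 genes of the authors' correction (one-sided hypergeometric test, Benjamini-Hochberg over 29 lists). This was added after the data were seen, because the number of tested genes could then be recovered. It assumes that every member was tested, and abundant genes, for which the authors' test has more power, pass more often. It also takes genes as independent, so its p-values are too small where members of a list move together. Counts adjusted over the list alone use the p-values of the authors.

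The alternatives fixed beforehand were the replicate number as a block, columns rescaled to equal median ratio over the listed genes, limma without trend, a mean of at least 50, pseudocounts of 0.5 and 10, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and each library left out in turn. edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads and the authors' own calls were added after the data were seen, as were the folds of called genes with each library left out, given where they moved by over 1.5 times. Libraries of the same genotype were compared by chi-square on the recovered reads. The value per degree of freedom ran from 7.42 to 84.9, so no pair agreed within sampling noise and each library was counted. It was highest between wild-type replicates 2 and 3. Across listed genes, which are not independent replicates, Pearson's r of log2(value + 1) was 0.934 to 0.972 within a genotype and 0.820 to 0.854 between genotypes. The first principal component, which parted the genotypes, held 79.2% of the variance. As the listed genes were selected for a difference between the genotypes, the lower r between them and this parting were built in. They say nothing about the genes not listed.

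The limma step was tested on simulated counts for the same 714 genes and 3 against 3 libraries. Of genes changed 4-fold, 45.0% passed, and 73.8% of those with a mean of at least 50. Of genes changed 2-fold, 0% passed. Of 514 unchanged genes 0 passed, and 192 of 200 changed genes had the right sign. edgeR passed 53.0% of the 4-fold genes. A gene that did not pass limma is therefore not shown to be unchanged. In simulations of the list tests, 2.25% of random lists passed an unadjusted p of 0.05 in the direction test and 1.5% in the over-representation test. Statistics and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.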

Results

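Messenger RNA was measured by RNA sequencing in 6 libraries of mouse bone marrow-derived macrophages. These are cells grown out of flushed bone marrow, here for 6 days with GM-CSF, a growth factor for myeloid cells, at 10 ng/ml. 3 libraries came from wild-type C57BL/6 cells and 3 from Senp8+/- cells, which carry 1 altered copy of Senp8, the gene of a protease that removes the ubiquitin-like protein NEDD8 from its targets. All 6 were given beads coated with CD47, the surface protein that binds the receptor SIRPα on macrophages and restrains engulfment, and RNA was taken 24 h later. No library without beads was analysed here, so every value describes cells exposed to CD47. The table used here holds 714 genes, chosen by the authors for an unadjusted p-value under 0.05 and at least a 2-fold difference between genotypes. Its values are normalised counts, that is, reads per gene divided by 1 size factor per library. The size factors were 0.971, 1.07 and 0.933 in the Senp8+/- libraries and 1.01, 0.947 and 1.14 in the wild-type libraries. The reads over the listed genes came to 213650, 217286 and 205957 in the Senp8+/- libraries and 491156, 468884 and 439026 in the wild-type libraries. These sums cover only the listed genes and are not the depth of the libraries, which is unknown here. Unless another error is named, values are mean normalised counts ± SD (n = 3 libraries per genotype). Nothing in the labels says that the 3 libraries of a genotype came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

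Senp8 itself (chromosome 9, 59734259 to 59750710 in GRCm38) was not analysed here, so the genotype labels were not checked against its level. None of the 33 genes of the neddylation and deneddylation list, which counts Senp8, was among the listed genes used here. So 0 were called, against 0.663 called genes expected by chance, too few for their absence to mean anything.

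The comparison of the genotypes asks which transcripts differ when macrophages with 1 altered Senp8 copy meet CD47. Most of the genes that differed were lower in Senp8+/- macrophages, and of the 29 gene lists antigen presentation held the most called genes. Cd74, the invariant chain that guides MHC class II molecules, fell from 33139 ± 2742 in wild type to 10403 ± 996 in Senp8+/-. H2-K1, a classical MHC class I heavy chain, fell from 55743 ± 11622 to 24065 ± 2403. Timd4, a receptor for phosphatidylserine on dying cells, fell 26.4-fold, from 179 ± 37.4 to 6.79 ± 2.48. Lrmda rose 13.8-fold, from 14.8 ± 2.53 to 203 ± 41.5, and Serpinb2, an inhibitor of plasminogen activators, rose 8.14-fold, from 61.6 ± 13.6 to 501 ± 89.7.

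Of the 714 listed genes, 145 lay higher and 569 lower in Senp8+/- than in wild type. The authors' deposited table gives 295 of them an adjusted p under 0.05, 53 higher and 242 lower. "Rose" and "fell" are used below for these genes, and "called" means the same. The other 419 listed genes did not pass. The 3 Senp8+/- values lay outside the range of the 3 wild-type values for 638 listed genes and for 295 of the 295 called genes. Chance gives 10% for 3 against 3 libraries, but the genes were selected on this comparison. limma, with the correction carried over 14694 genes, placed 176 listed genes past an adjusted p of 0.05, 27 higher and 149 lower, of which 156 were among the authors' calls. That count came to 100 without Senp8+/- replicate 1, 37 without Senp8+/- replicate 2, 87 without Senp8+/- replicate 3, 11 without wild-type replicate 1 and 112 without wild-type replicate 2. Rescaling the libraries to equal medians over the listed genes raised each log2 fold change by about 1.27 and so made 87.1% of the limma calls higher, against 15.3% at the deposited scaling. The sign turned for 147 listed and 51 called genes, and members of the lists that turned are named with their groups where they are reported. The listed genes cannot give a scaling, and every gene was shifted by about the same amount. A turned sign therefore marks only a fall smaller than that shift.

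**Figure D1:**
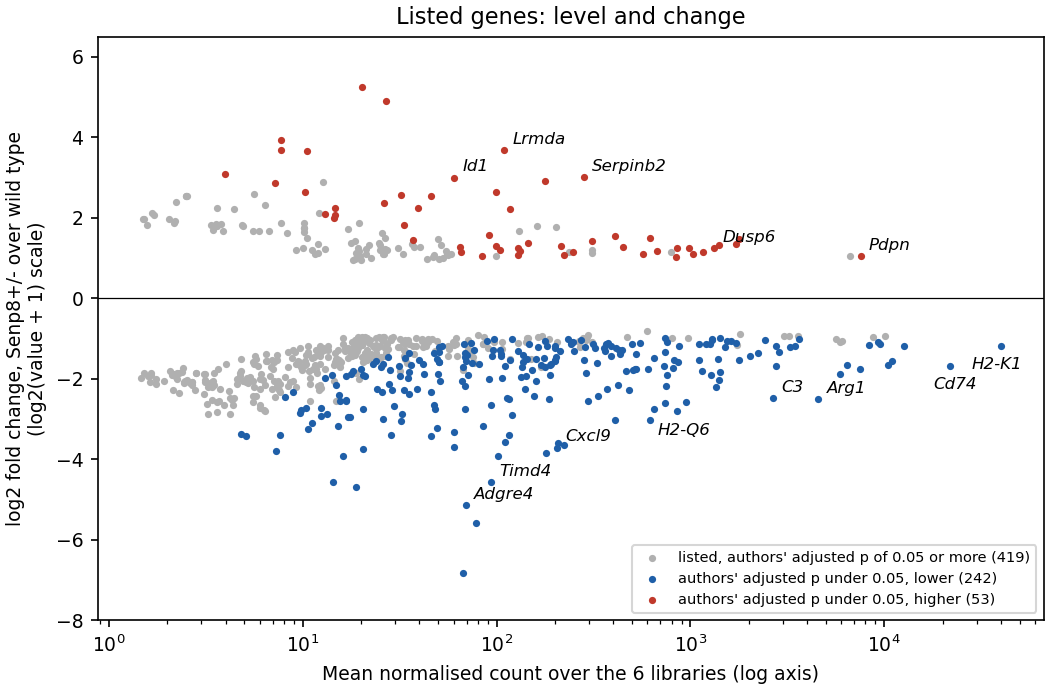
Each point is 1 of the 714 listed genes, with its mean normalised count over the 6 libraries on a log axis against its log2 fold change, Senp8+/- over wild type, on the log2(value + 1) scale. The 242 called genes below 0 outnumber the 53 above it, and of the genes labelled in the plot only H2-K1 turned sign when the libraries were rescaled over the listed genes.

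The antigen presentation list had 28 genes, and 19 of them were listed, all lower in Senp8+/-. 15 of the 19 fell, against 0.562 expected by chance among the called genes (one-sided hypergeometric test, adjusted p = 2.09e-17 over 29 lists, the test behind the other list p-values below), and 19 passed when adjusted over the list alone. The hypergeometric test takes genes as independent, so members that move together make its p-values too small. H2-K1, Tap1, H2-DMb1, Tapbp, Psmb9, Psmb8 and Psmb10 turned sign under the rescaling. Besides Cd74, the MHC class II chain H2-Aa fell from 15974 ± 4437 to 4917 ± 656. The non-classical class I genes H2-Q6, H2-Q4 and H2-Q7 fell from 1097 ± 104 to 135 ± 21.5, from 2216 ± 138 to 482 ± 75.6 and from 1133 ± 342 to 167 ± 43.0. These genes are near-identical neighbours on chromosome 17, so the counting could have split their reads, and the value of each is uncertain. Ciita and H2-Ab1, chosen after their values were seen, are the master regulator and a chain of MHC class II. Ciita fell from 411 ± 217 to 32.6 ± 20.5 (21.1 without Senp8+/- replicate 1) and H2-Ab1 from 11607 ± 2972 to 3381 ± 599. limma gave Cd74 a log2 fold change of -1.67 ± 0.20 (SE; adjusted p = 0.00145) and H2-Q6 one of -3.03 ± 0.28 (SE; adjusted p = 2.50e-04). H2-Q6 (ENSMUSG00000073409) lies on chromosome 17 from 35424850 to 35430055 and Cd74 (ENSMUSG00000024610) on chromosome 18 from 60803848 to 60812646.

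Interferon response genes went both ways. Of the 59 genes in the list, 14 were listed and 13 were called, 10 lower and 3 higher (adjusted p = 1.70e-09, hypergeometric), with 14 past when adjusted over the list alone. Irf7, Gbp3, Gbp5 and Ifitm3, all lower, turned sign under the rescaling. Cxcl9, a chemokine for activated T cells, fell from 383 ± 161 to 27.6 ± 9.86. The guanylate-binding protein gene Gbp4 fell from 205 ± 103 to 15.1 ± 0.9997, and the GTPase genes Iigp1 and Tgtp2 fell from 557 ± 44.4 to 106 ± 32.6 and from 934 ± 219 to 276 ± 58.9. The 3 that rose were Ifit3b, Ifit1 and Usp18, of which the last 2 were named after their values were seen. Ifit3b rose from 44.4 ± 9.22 to 137 ± 47.4, Ifit1 from 557 ± 124 to 1129 ± 176 and Usp18, a protease for the ubiquitin-like protein ISG15, from 363 ± 80.0 to 776 ± 133. Tgtp2 and Ifit3b have near-identical neighbours, Tgtp1 and Ifit3, with which they can share reads.

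Genes of inflammatory and of alternatively activated macrophages were both among those that fell. In the inflammatory list, 9 of 30 genes were listed, all lower, and 7 fell (adjusted p = 1.62e-05). In the alternative-activation list, 9 of 34 were listed, 8 lower and 1 higher, and 7 fell (adjusted p = 3.00e-05). The counts adjusted over the list alone were 9 and 8. Marcksl1, Saa3 and Il27 of the first list and Flt1 of the second turned sign under the rescaling. Nos2, the inducible nitric oxide synthase, fell from 112 ± 53.4 to 8.39 ± 6.33 (4.86 without Senp8+/- replicate 1), and the formyl peptide receptor Fpr2 from 214 ± 80.4 to 26.2 ± 0.537. Cd38 fell from 287 ± 32.1 to 90.9 ± 19.4, and the transcription factor Irf1 from 4082 ± 420 to 1655 ± 476. Arg1, the arginase that shares its substrate with Nos2, fell from 7823 ± 3356 to 1289 ± 101. Ccl22, Retnla and Ear2 fell 2.71-, 3.08- and 3.89-fold. Il10, named after its value was seen, was not called at 9.62 ± 4.67 in Senp8+/- and 2.22 ± 1.02 in wild type.

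**Figure D2:**
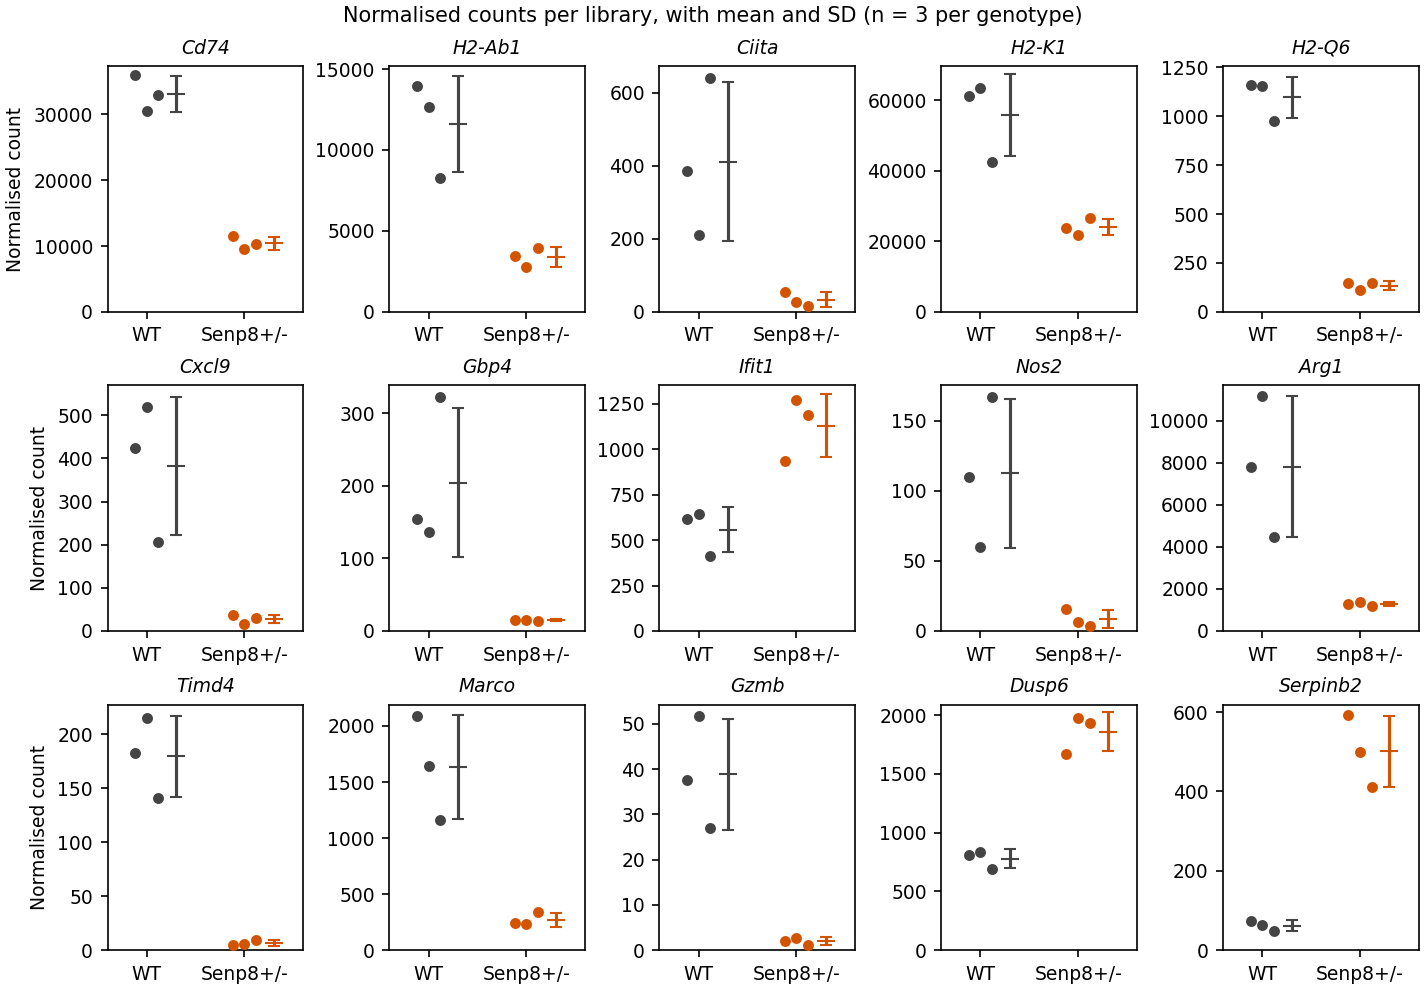
Normalised counts of 15 genes in each library (points), with mean and SD beside them (n = 3 per genotype), on linear axes that start at 0. In each panel the 3 Senp8+/- libraries lie on 1 side of the 3 wild-type libraries, higher for Ifit1, Dusp6 and Serpinb2 and lower for the other genes, of which H2-K1 turned sign when the libraries were rescaled over the listed genes.

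Among chemokines and their receptors, 8 of 38 genes were listed and 7 were called, 6 lower and 1 higher (adjusted p = 5.25e-05; 8 adjusted over the list alone). Ccl5 fell from 1225 ± 204 to 269 ± 18.4 and Ccl8 from 215 ± 127 to 16.8 ± 0.715. Cxcl14 rose from 935 ± 253 to 2647 ± 900. In the list of T cell co-signalling, which holds ligands and also enzymes, 7 of 21 genes were listed, 5 lower and 2 higher. 5 fell (adjusted p = 2.38e-04; 6 adjusted over the list alone). Those that fell included the enzymes Arg1 and Nos2, given above, which are not ligands and had the smallest p-values of the list. They also included Cd86, which fell from 615 ± 211 to 243 ± 28.1, and Vsig4, a complement receptor, which fell from 368 ± 195 to 135 ± 12.6. 5 of the 7 also stand in other lists.

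Of 41 phagocytosis genes, 5 were listed, all lower, and 4 fell (adjusted p = 0.0261; 4 adjusted over the list alone), with Cd300lf and Stab2 turning sign under the rescaling. Besides Timd4, the scavenger receptor Marco fell from 1631 ± 465 to 271 ± 61.6, the Fc receptor Fcgr4 from 4254 ± 1616 to 1260 ± 117 and Cd300lf from 2338 ± 490 to 1080 ± 132. The list of CD47, SIRPα and SHP phosphatase signalling was not over-represented among the calls (adjusted p = 0.127; 3 adjusted over the list alone). Of its 21 genes 4 were listed, all lower, and 2 fell, while Clec12a turned sign under the rescaling. Thbs1, a secreted ligand of CD47, fell from 2267 ± 1291 to 590 ± 178, and the sialic acid receptor Siglec1 from 2169 ± 1833 to 620 ± 156. Without wild-type replicate 3 the Siglec1 mean in wild type was 1124, and the fall came to 1.81-fold in place of 3.50-fold. Clec12a stood at 3808 ± 840 in Senp8+/- and 8288 ± 3210 in wild type, and Siglecg at 8.08 ± 2.80 and 18.9 ± 2.04.

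Among 27 matrix and protease genes 3 were listed, and each was called (adjusted p = 0.0397; 3 adjusted over the list alone). Serpinb2 and Timp1 rose and Thbs1 fell. Timp1, an inhibitor of matrix metalloproteinases, rose from 174 ± 78.4 to 447 ± 131. Dusp6, a phosphatase of ERK and a target gene of that pathway, rose from 779 ± 80.3 to 1860 ± 164. It was the 1 called gene of 28 immediate early and ERK target genes (adjusted p = 0.629; 1 adjusted over the list alone), of which 3 were listed. Egr1 stood at 240 ± 59.3 in Senp8+/- and 84.6 ± 67.8 in wild type, and Fosl1 at 67.3 ± 16.2 and 33.4 ± 2.15. Idi1, a gene of sterol synthesis, rose 2.07-fold, from 676 ± 247 to 1397 ± 201. Of 34 hypoxia and glycolysis genes 4 were listed, all lower, and Egln3, Slc16a3 and Ankrd37 fell 5.49-, 2.04- and 3.32-fold, with Slc16a3 turning sign under the rescaling (list adjusted p = 0.0676; 4 adjusted over the list alone). P4ha2 stood at 19.5 ± 7.64 in Senp8+/- and 49.4 ± 5.68 in wild type.

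3 more lists had 1 or 2 listed genes. Cd83 of the NF-kB list and Cdkn1a of the cell cycle list fell 2.004- and 2.11-fold, and both turned sign under the rescaling (list adjusted p = 0.626 and 0.849; 1 in each adjusted over the list alone). Cdc25c of the cell cycle list stood at 19.8 ± 9.73 in Senp8+/- and 4.53 ± 4.72 in wild type. Scd1 of the lipid list stood at 331 ± 160 and 142 ± 51.5 (0 adjusted over the list alone). The lists of NRF2 targets, oxidative phosphorylation, ER and heat stress, and lysosome had 0 listed genes, as had neddylation. A gene that is not listed had a p of 0.05 or more or a fold difference under 2 in the authors' test, was not tested, or was not used here, and these cannot be told apart for a single gene.

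Genes outside the lists that moved most were chosen by the rule fixed before the data were examined. Id1, an inhibitor of helix-loop-helix transcription factors, stood at 112 ± 86.1 in Senp8+/- and 8.86 ± 2.40 in wild type and rose 12.6-fold, or 8.39-fold without Senp8+/- replicate 3. Trim13, Tmeff1, Mid1 and the CDK inhibitor gene Cdkn2b rose 7.24-, 6.74-, 4.57- and 3.44-fold. At higher levels, podoplanin (Pdpn) rose from 4976 ± 1170 to 10142 ± 649.7, the hepatocyte growth factor receptor Met from 1001 ± 488 to 2421 ± 550 and Spryd7 from 837 ± 348 to 1977 ± 158. The adhesion receptor Adgre4 fell from 136 ± 47.2 to 3.11 ± 1.89, Loxl2 from 190 ± 56.1 to 11.8 ± 4.04 and Ly6i from 339 ± 129 to 21.7 ± 6.38. Npas4 fell from 59.99 ± 72.1 to 3.93 ± 2.31, a 15.3-fold fall that came to 4.67-fold without wild-type replicate 3. Lgals3bp fell from 17498 ± 1553 to 7672 ± 373 and turned sign under the rescaling, and Ly6e fell from 16420.3 ± 2089 to 5512 ± 125. Ly6i and Ly6c2 belong to a family of close copies, so their reads are uncertain.

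Markers of other cell types moved with the genotype. Of 22 T and NK cell genes, 8 were listed, all lower, and 4 fell (adjusted p = 0.00317; 7 adjusted over the list alone). Their levels were low. Gzmb fell from 38.8 ± 12.4 to 1.97 ± 0.863 and Prf1 from 19.6 ± 4.13 to 1.68 ± 2.16 (0.465 without Senp8+/- replicate 1). Gzma and Ncr1 had 0 reads in the Senp8+/- libraries and 28.6 ± 18.7 and 10.2 ± 3.58 in wild type, at least 9.42- and 3.37-fold lower against a floor of 3 reads per library. Of 22 neutrophil genes 4 were listed and each fell (adjusted p = 0.00317; 4 adjusted over the list alone). Ly6c2 fell from 382 ± 150 to 30.7 ± 12.7, Csf3r from 1285 ± 232 to 434 ± 110 and Prtn3 from 14.6 ± 6.62 to 1.66 ± 0.522, and Retnlg, with 0 reads in Senp8+/-, was at least 4.80-fold lower. Of 19 monocyte and progenitor genes 5 were listed and 3 fell, namely Ly6c2, Plac8 and Hp (adjusted p = 0.0197; 4 adjusted over the list alone). Of 23 stromal genes 9 were listed, all lower, and 3 fell (adjusted p = 0.0278; 5 adjusted over the list alone), while Col1a2, Dcn, Pdgfra, Fbn1 and Col1a1 turned sign. Thy1 fell from 30.7 ± 6.29 to 3.45 ± 2.58 (1.96 without Senp8+/- replicate 3), Col3a1 from 299 ± 192 to 82.3 ± 20.9 and Pecam1 from 20.02 ± 4.63 to 2.37 ± 3.33 (0.465 without Senp8+/- replicate 1), while Col1a2 stood at 154 ± 65.2 in Senp8+/- and 387 ± 206 in wild type.

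Of 20 dendritic cell genes 2 were listed and both fell, Clec9a from 82.8 ± 11.5 to 12.5 ± 3.64 and Ccl22 as above (adjusted p = 0.125; 2 adjusted over the list alone). The mast cell gene Tpsab1 rose from 1.96 ± 1.73 (0.965 without wild-type replicate 1) to 18.6 ± 10.8 as the 1 listed gene of 22 (list adjusted p = 0.580; 1 adjusted over the list alone). Car2 of the erythroid and megakaryocyte list rose from 218 ± 93.1 to 596 ± 61.1, and Klf1 stood at 0.620 ± 1.07 in Senp8+/- and 6.06 ± 3.95 in wild type (list adjusted p = 0.498; 1 adjusted over the list alone). The B cell gene Cd79b stood at 11.7 ± 0.881 and 34.8 ± 10.7 (1 adjusted over the list alone). Of 23 macrophage and osteoclast genes, C1qa and C1qc were the 2 listed and neither was called (2 adjusted over the list alone). C1qa stood at 3654 ± 904 in Senp8+/- and 7678 ± 2877 in wild type, C1qc at 5707 ± 1041 and 11766 ± 4719, and both turned sign under the rescaling.

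The share of listed genes that were called differed between chromosomes, as was seen after the data were examined. How many genes were tested per chromosome is unknown here, so this does not show where calls lay among all tested genes. On chromosome 14, 28 of 38 listed genes were called (73.7%), 21 lower and 7 higher, against 267 of 676 elsewhere (39.5%), and 2 of the 28 turned sign under the rescaling. Chromosome 14 held Lrmda (22019712 to 23056085), Spryd7 (61531993 to 61556886), Trim13 (61598247 to 61605946), Gzmb (56258838 to 56262260) and Loxl2 (69609068 to 69695834). Sorbs3 (70180468 to 70211989), named after its value was seen, fell from 732 ± 356 to 85.2 ± 33.2.

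**Figure D3:**
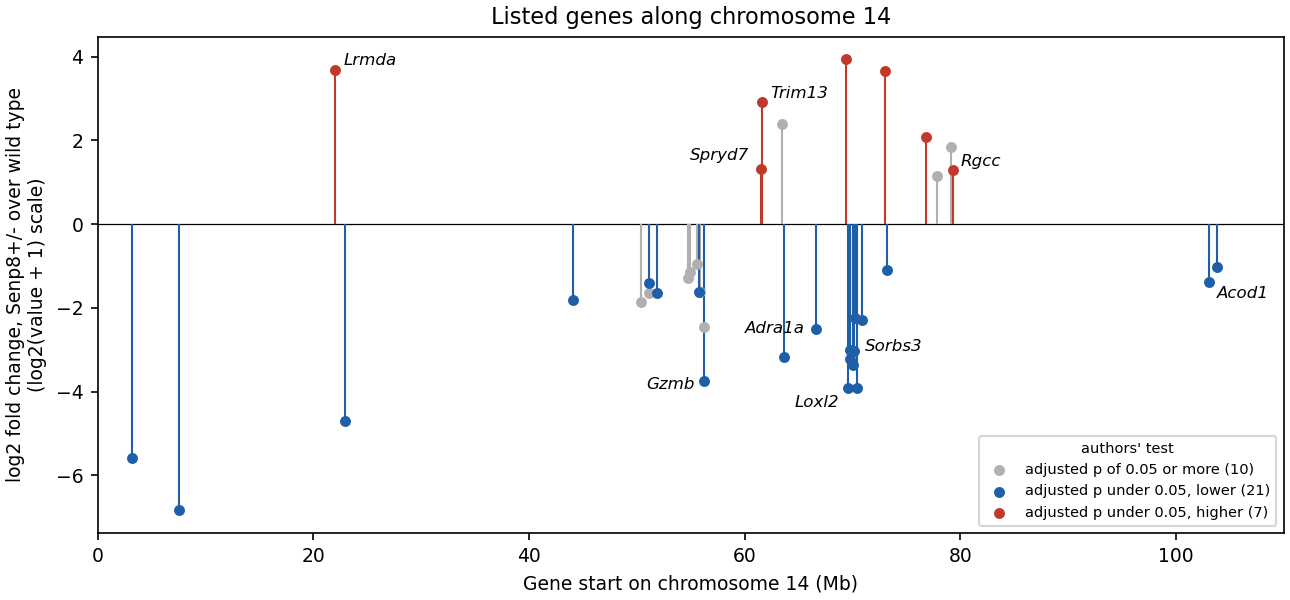
Each stem is 1 of the 38 listed genes on chromosome 14, at its start in Mb (GRCm38), with its log2 fold change, Senp8+/- over wild type, on the log2(value + 1) scale. 21 called genes lie below 0 and 7 above, and 17 of the 28 start within 20 Mb of each other, and 2 of the 21 turned sign when the libraries were rescaled over the listed genes.

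In all, 12 of the 29 lists were over-represented among the authors' calls, and 9, 9 and 13 among the calls of limma, edgeR and DESeq2. Among limma's calls the number was 7, 4 and 6 without Senp8+/- replicates 1, 2 and 3, and 0, 5 and 11 without wild-type replicates 1, 2 and 3. This test was added after the data were seen and takes each list member as tested by the authors and as independent of the others. The planned test asked whether the up and down split of a list differed from that of the other listed genes, and 0 of 10 lists with at least 5 listed genes passed (two-sided Fisher exact test). The smallest adjusted p was 0.192, for antigen presentation, which was the 1 list with an unadjusted p under 0.05 (Fisher exact p = 0.0192). All 19 of its listed genes were lower. As 569 of the 714 listed genes were lower, even a list with every member lower could hardly pass. The result therefore does not show that no list leaned lower.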

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

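The edgeR, DESeq2 and authors' counts and the over-representation test were chosen after the data were seen. limma's 176 genes past the threshold became 73 with a mean of at least 50 and 74 at an adjusted p under 0.01, both by fewer genes admitted, 11 to 181 with each library left out (11 without wild-type replicate 1, the cause was not tested) and 295 by the adjusted p of the authors. They stayed within 1.5 times under limma without trend (145), pseudocounts 0.5 and 10 (154 and 151), rescaling (155, 135 of them higher), a minimum absolute log2 fold change of 1 (176), edgeR (180) and DESeq2 (235), and 140 genes passed all 3 tools and the authors' test. With the replicate number as a block the count was 174. Same-numbered libraries did not deviate together over the listed genes (r across genes of 0.01, 0.04 and -0.24 for numbers 1, 2 and 3), and not every library correlated best with its own number. With 3 libraries per genotype this cannot exclude that same-numbered libraries were handled together. The over-represented lists numbered 12 by the authors' calls and 9 by limma's, and limma's count ran from 0 to 11 with each library left out (0 without wild-type replicate 1 and 11 without wild-type replicate 3), the cause not tested. No list (0) passed the direction test under any alternative run, but that test could hardly pass a list whose members lay lower. The lowest correlation within a genotype was 0.945 with a pseudocount of 10. Rescaling over the listed genes, whose construction shifts every fold change upward, turned these to above 0: H2-K1 log2 fold change 0.0795, Lgals3bp log2 fold change 0.0864, Clec12a log2 fold change 0.21, Cd300lf log2 fold change 0.17, Cd83 log2 fold change 0.27, Slc16a3 log2 fold change 0.25, Cdkn1a log2 fold change 0.21, Col1a2 log2 fold change 0.0628, C1qa log2 fold change 0.26 and C1qc log2 fold change 0.31. No other alternative turned the sign of a named gene. Of the 82 named genes reported, 40 kept their side of limma's threshold without wild-type replicate 1 and 52 without Senp8+/- replicate 2, 77 did under edgeR and 73 with the block. Under the rescaling 29 did, while 28 lost the call, 15 gained it and 10 turned sign. Not run were the level of Senp8, gene list tests with an estimated correlation, and TMM against DESeq2 size factors, which need rows or totals not used here. Library depths are unknown here, so what depth limits was not measured. Simulated 2-fold changes were not recovered by limma (0%), in a simulation whose threshold was stricter than that in the data.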

Other observations

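All tests in this part were chosen after the results were seen, except the count of other splits of the libraries. A group outside the lists fixed beforehand was complement. Of 30 complement genes and receptors, 11 were listed, all lower, and 9 fell, against 0.602 expected by chance (exact one-sided hypergeometric p = 4.64e-09). The list was drawn up after the calls were seen, and the p is not adjusted for other groups that could have been picked. It is therefore a description and not a measure of chance. C1qa and C1qc, the other 2, turned sign when the libraries were rescaled over the listed genes. C3, the central component, fell from 4528 ± 1435 normalised counts in wild type to 786 ± 107 in Senp8+/- (SD, n = 3). Factor B (Cfb) fell from 120 ± 20.98 to 17.6 ± 6.70, C4b from 802 ± 312 to 157 ± 34.6 and C1ra from 455 ± 78.7 to 126 ± 24.1. C1s1, Serping1, Vsig4, Cd55 and C2 fell 4.48-, 3.999-, 2.73-, 3.24- and 5.63-fold, the last 11.8-fold without Senp8+/- replicate 1. Markers of other cell types moved in the same libraries: 3 of 9 listed stromal genes and 3 of 5 listed monocyte and progenitor genes fell. So did 4 of 4 listed neutrophil, 4 of 8 T and NK cell and 2 of 2 dendritic cell genes. The mast cell gene Tpsab1 and Car2 of the erythroid and megakaryocyte list rose. No listed gene of the B cell list or of the macrophage and osteoclast list was called. Macrophage genes of other lists did fall, 7 of 9 listed in the inflammatory list and 7 of 9 in the alternative-activation list.

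Among 8 genes of cyclin-dependent kinase inhibitors 4 were called, 2 in each direction (exact one-sided hypergeometric p = 1.05e-05). This list too was drawn up after the calls were seen, so its p is only a description. Cdkn1a and Cdkn1c fell 2.11- and 2.12-fold, and both turned sign under the rescaling. Cdkn2a and Cdkn2b, which lie next to each other on chromosome 4, rose 2.67- and 3.44-fold. Ifi208 and Gm17121 had no reads in 1 genotype. Ifi208 stood at 40.5 ± 22.2 in Senp8+/- and 0 in wild type, at least 13.9-fold higher, and the predicted gene Gm17121 stood at 134 ± 100.2 in wild type and 0 in Senp8+/-, at least 44.1-fold lower, or at least 25.1-fold without wild-type replicate 2.

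The fall of antigen presentation and GBP genes went with lower T and NK cell transcripts, and T and NK cells in the wild-type cultures could bring both. The called antigen presentation genes fell by 97145 normalised counts in all, and the 8 listed T and NK genes by 142, a ratio of 686 (574 to 783 over the wild-type libraries), which argues against RNA of T and NK cells themselves as the source of the fall. A wrong scaling of the libraries would shift most genes. Of the 14694 genes in the authors' correction, 9.58% had a p under 0.05. That share goes against a shift large enough to bring most genes to such a p. A smaller scaling error need not do so with 3 libraries per genotype and stays open. Less interferon gamma, which T and NK cells release, may account for the pattern: within the interferon list fixed beforehand, which leaves out some GBP genes, the 8 listed members that are Cxcl9 or of the GBP and IRG families were lower, whereas of its other listed genes 4 were higher and 2 lower (two-sided Fisher exact p = 0.0150), with Gbp3 and Gbp5 of the first set and Irf7 and Ifitm3 of the other turning sign under the rescaling. That test cannot be decisive, since the genes were divided after their directions were seen, and an effect of Senp8 in the macrophages stays open and untested, as do fewer B or dendritic cells, both rich in MHC class II, whose markers Cd79b (11.7 in Senp8+/- and 34.8 in wild type, not called) and Clec9a (12.5 and 82.8, called) were lower.

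On chromosome 14, 28 of 38 listed genes (73.7%) were called against 267 of 676 elsewhere (39.5%; two-sided Fisher exact p adjusted over 23 chromosomes and scaffolds = 0.00131; chromosome 17, which holds the MHC, had 34 of 54, adjusted p = 0.0156). Listed genes were selected on the same test as the calls, and the number tested per chromosome is unknown here. The larger share therefore does not show that calls gathered on chromosome 14 among all tested genes. Calls shuffled over the listed genes gave a chromosome as extreme with a permutation p of 0.0003 (10000 permutations). The shuffle takes genes as independent, whereas neighbours can move together or share reads. It therefore argues against chance position of the calls only among the listed genes, and only for independent genes. Among named protein-coding genes alone 20 of 29 (69.0%) were called against 245 of 567 (43.2%), with a permutation p over the chromosomes of 0.0695, so reads shared with pseudogenes or predicted genes stay open as part of the pattern. A segment of another strain on chromosome 14 may be a source: in the 20 Mb with most calls (51123908 to 70979838, 17 called genes, among them Loxl2, Sorbs3, Gzmb and Trim13) 3 were higher and 14 lower, and 5 had a genotype mean under 3.3 normalised counts. Without genotypes of these cells that cannot be told apart from an effect of Senp8, which lies on chromosome 9. Within 10 Mb of Senp8 itself, 1 of 7 listed genes was called.

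Genes on the Y chromosome and at the far end of X were higher in Senp8+/-. Ddx3y, Eif2s3y and Uty rose 2.77-, 2.34- and 2.07-fold, by log2 fold changes at most 0.988 standard errors apart, as 1 common factor requires. A lower share of male cells in the wild-type libraries could bring such a factor. All 3 were listed only after passing a cut of at least 2-fold. Y genes that differ less were left out, so the test cannot decide. The sex-linked genes Xist and Kdm5d were not among the listed genes, so neither was used as a check. The ratio of Ddx3y to Eif2s3y ran from 0.469 to 1.07 over the wild-type libraries and from 0.708 to 0.797 over the Senp8+/- ones. Mid1, G530011O06Rik, Gm21887 and Gm15726 (X, 169685199 to 170019281), beside the pseudoautosomal region, rose, as did Gm47283 on Y, from 0.934 ± 0.880 (0.528 without wild-type replicate 3) to 52.6 ± 4.22, its lowest Senp8+/- value being 16.5 times the wild-type floor of 3 reads per library, and of the other 17 listed X genes 8 (47.1%) were higher, against 18.7% of the listed autosomal genes (two-sided Fisher exact p = 0.00830). A lower share of male cells in wild type would raise no gene by more than Ddx3y, Eif2s3y and Uty rose. Yet the mean log2 level of the 4 distal X genes over that of these 3 was 1.12 ± 0.25 (SE) higher in Senp8+/- (-3.41 to -2.77 over the libraries, against -4.44 to -3.86 in wild type). The share of male cells alone therefore accounts neither for these X genes nor for Gm47283. A strain difference in that region was not tested, and the sex of the animals is not given in the sources used here.

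limma called 176 genes for the real split of the 6 libraries and at most 0 for the other 9 splits, so 1 of 10 splits gave as many. At an unadjusted p under 0.05 the real split had 702 genes and the others 2 to 24. With 10 splits the share cannot go under 0.05, and the genes listed were selected on the real split.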
